A study of Mus musculus with 2 samples.

How the data were processed

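The samples were intestinal stem cells from Lgr5-EGFP-IRES-creERT2 mice, in which the Lgr5 locus, active in stem cells at the crypt base, drives a green fluorescent protein. Cells of high GFP were sorted into Trizol, and 1 ug of total RNA entered the Illumina TruSeq RNA Sample Prep Kit, per the labels' protocols. There was 1 library from mice of 4 months fed chow ad libitum and 1 library from fasted mice of the same age. The labels give neither the length of the fast nor the number of mice behind each library.

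Before deposit the authors counted reads per Ensembl gene in each library, and these deposited counts are whole numbers that were not normalised. FastQC, STAR, HTSeq and DESeq are named, without versions, roles or order, per the submitters' processing notes, which also name the genome builds GRCm38 and mm10. The gene annotation and the strand setting of the counting are not given in the sources used here, so reads of overlapping and antisense genes cannot be told apart. A further deposited table, named for normalised gene counts per the file headers, holds for each library a signal that equals its count divided by 1 factor per library. The factors recovered from this table were 1.19 for the fed and 0.842 for the fasted library. Multiplied by them, the values gave back whole reads: the deposited counts divided by the factors matched 100% of the values within 0.0051. Ratios taken from that table gave the same 302 higher and 230 lower genes in number as the counts themselves.

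The files list 45706 gene IDs, of which 45143 were matched to a symbol of GENCODE release M21, an annotation of GRCm38 that also supplied gene types, exon lengths and coordinates. No column lacked a sample, and no line of the files held reads outside genes. Counts were divided by median-of-ratios size factors (1.19 and 0.842), the method of the DESeq program. For each gene the log2 ratio of fasted to fed was computed with an exact 95% Clopper-Pearson interval, taken from the fasted share of the gene's reads. These intervals and the floor below cover counting error only. Genes with a mean of at least 1 count per 1000000 counts of the library (CPM) and a summed count of at least 20 were called measured. A gene was called higher or lower in the fasted library when its ratio was at least 2-fold and its interval excluded a ratio of 1. A gene without a count in 1 library was given a bound, computed against a floor of 3 counts in that library, which corresponds to 0.429 CPM in the fed and 0.598 CPM in the fasted library. With 1 library per group there was no test and no p-value, and every difference describes these 2 libraries.

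Before the data were examined, 27 gene lists, 11 lists of cell type markers and the rule for naming genes were fixed. For each list with at least 3 measured members the median log2 ratio was taken. Its percentile was found among 10000 random lists of the same size, matched in 20 bins of mean expression and drawn with a fixed seed. A list was said to stand apart when its percentile lay below 2.5 or above 97.5. Random lists were not matched on length or on shared regulation, and members of a pathway vary together, so a percentile describes these libraries and is no p-value. An interval for a median, called its counting interval, was obtained by redrawing the counts. The named genes are the 15 highest and 15 lowest protein-coding genes among those of at least 5 CPM, ranked by the interval bound nearest to 0, without predicted genes and pseudogenes. To these were added up to 4 members with the largest log2 ratio in either direction from each list, members past the threshold in lists of fewer than 10, and fixed genes, among them Lgr5, Olfm4, Ascl2, Mki67, Cpt1a, Pdk4, Acot1, Angptl4, Ppara, Ppard, Pparg and Ppargc1a. Some genes that the rule takes are not reported here, in the text or by name in the figures. Any other gene is said to have been chosen after its values were seen. The 4 lists in the closing section (proximal small intestine, ileum and colon, interleukin response, peroxisome) were added later.

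The procedure was tested on simulated counts for the fasted against fed comparison, drawn for 11999 genes from the means and library sizes of the real data. It called 66 of 66 genes changed 8-fold (100%), 66 of 67 changed 3-fold (98.5%) and 2 of 67 changed 1.5-fold (2.99%), all in the right direction. Of 11799 unchanged genes, 54 were called (0.458%), and the intervals held the true ratio for 95.4% of genes. These simulated counts vary by counting alone, as real replicates would not.

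Alternatives tried were TMM factors (edgeR 4.0.16), total counts, upper-quartile factors, the deposited normalised values, no low-count filter, a minimum of 5 CPM, thresholds of 1.5-fold and 3-fold, an interval bound of at least 2-fold, 5 bins for the random lists, summed counts of a list's members and a pseudocount of 0.1 in place of 1. After the data were seen, a correction of the log2 ratios for exon length (a running median over 20 bins) and list medians over members that no other list holds were added. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, R 4.3.3, and matplotlib 3.10.9 for the figures. No data were left out.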

Results

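Gene expression was measured by RNA sequencing in intestinal stem cells, sorted for high GFP from Lgr5 reporter mice that were 4 months old. 1 library came from mice with free access to chow and 1 from fasted mice. The comparison asks how fasting alters the expression programme of these cells, in particular the genes of fatty acid oxidation. The fed library held 6985316 counts over 17970 genes and the fasted library 5020056 counts over 17067 genes, so that 1 count equalled 0.143 and 0.199 counts per 1000000 counts of its library (CPM). The difference between the libraries has no replicate check. Each ratio below is fasted over fed after scaling, and its 95% interval covers counting error only. Of a single gene, "higher" and "lower" denote a ratio of at least 2-fold with an interval that excludes 1, while a list is described by the median of its members.

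Genes of fatty acid oxidation and of lipid handling were higher in the fasted library as lists, with medians of 2.52-fold and 1.67-fold. Pdk4 and Angptl4, targets of fatty acid receptors named PPARs, were 31.1-fold and 28.4-fold above the fed level. Absorptive enterocyte markers were higher as well (13 of 20 higher, median log2 ratio 1.17). Scd2 and the gasdermin gene Gsdmc4 were lower, the latter 47.4-fold. Of 12026 measured genes, 302 were higher in the fasted library, 230 were lower and 11494 (95.6%) were neither. At least 4-fold differences were found for 66 higher and 51 lower genes, and at least 8-fold differences for 27 higher and 10 lower genes. The higher genes took 0.837% of the counts in the fed library and 2.93% in the fasted library, while the lower genes took 0.892% and 0.379%. Across the measured genes, which are not independent replicates, the libraries had a Spearman correlation of 0.979 and a Pearson correlation of 0.974. In 100 simulated draws with counting error alone, a mean of 20.6 genes passed as higher and 24.7 as lower. Real replicates vary more than that. In the most abundant of 5 equal bins of genes the log2 ratios had a robust SD of 0.228 around their median, against 0.0659 from counting, and how much of this is variation between mice is unknown.

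**Figure D1:**
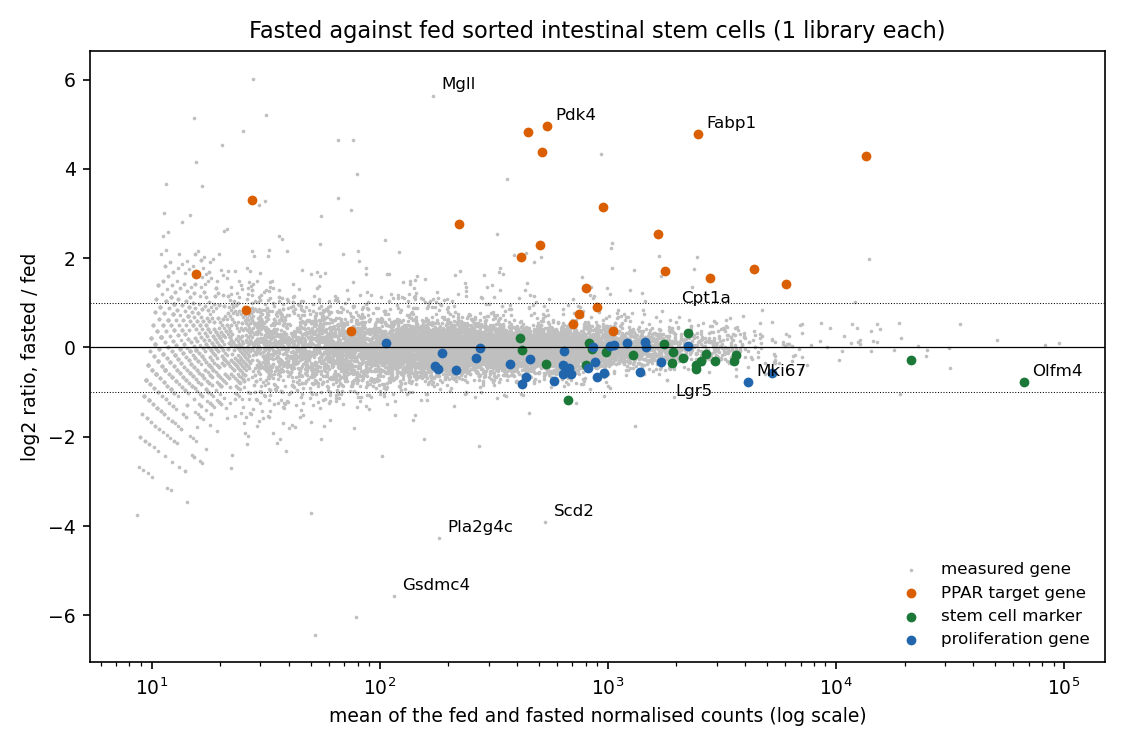
Log2 ratio of fasted to fed against the mean of the fed and fasted normalised counts (log scale), 1 point per measured gene, with dotted lines at 2-fold. PPAR target genes (orange) lie above 0, with Fabp1 at 4.78, while stem cell markers (green) and proliferation genes (blue) lie mostly below 0 and within 2-fold, as Olfm4 at -0.78. Cyp4a10 had no fed count and is not drawn.

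Fatty acid oxidation genes were higher as a group. Of 27 measured members 16 were higher, 0 were lower and all 27 had a positive log2 ratio. The median was 1.34 (2.52-fold, counting interval 1.16 to 1.38), and 0 of 10000 matched random lists had a median as high. The 15 members that no other list holds had a median of 0.78, with 7 higher. Cpt1a, whose product controls the entry of long-chain fatty acids into mitochondria (chromosome 19, 3322334 to 3385733, GRCm38), went from 1689 to 3526 counts, a log2 ratio of 1.56 (1.48 to 1.64). Slc25a20, which carries acylcarnitines across the inner mitochondrial membrane, had 2.29 (2.07 to 2.53), and the long-chain acyl-CoA dehydrogenase gene Acadl had 2.53 (2.40 to 2.66). The thioesterase genes Acot1 and Acot2 had 3.14 (2.94 to 3.35) and 2.76 (2.38 to 3.16). They are near-identical neighbours on chromosome 12, so the split of reads between them is uncertain.

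Targets of the peroxisome proliferator-activated receptors (PPARs), which are nuclear receptors for fatty acids, showed the highest median of all lists. Of 24 measured members 18 were higher and 0 were lower, with a median of 1.89 (3.70-fold, counting interval 1.79 to 2.24) and 0 of 10000 random lists as high. The 6 members that no other list holds had a median of 2.91, with 4 higher. Pdk4, a kinase that inhibits pyruvate dehydrogenase (chromosome 6, 5483351 to 5496309), went from 40 to 880 counts, a log2 ratio of 4.96 (4.50 to 5.45). Angptl4, an inhibitor of lipoprotein lipase, had 4.83 (4.34 to 5.35), the fatty acid binding protein gene Fabp1 had 4.78 (4.58 to 4.99) and the transcription factor gene Creb3l3 had 4.38 (3.99 to 4.80). Cyp4a10, a fatty acid hydroxylase gene, had 0 counts in the fed and 85 in the fasted library, at least 40.0-fold higher when set against the floor of 3 counts, and its counting interval began at a log2 ratio of 4.99. Its reads may be shared with Cyp4a32, and counts summed over all Cyp4a genes, a family chosen after the values were seen, went from 9 to 114, a log2 ratio of 4.16 (3.19 to 5.33). The receptor genes themselves stayed within 2-fold. Ppara had a log2 ratio of 0.75 (0.44 to 1.07), Ppard -0.72 (-0.89 to -0.56), and Pparg 0.39 (-0.19 to 0.97), while the coactivator gene Ppargc1a had 0.47 (0.12 to 0.81). In the same library, markers of absorptive enterocytes were also higher, with a median of 1.17. Stem cell markers had a median of -0.23, with 19 of 23 negative and 1 lower past 2-fold.

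Of 6 measured ketone body genes 1 was higher and 0 were lower, with a list median of 0.26 (percentile 98.3). The 5 members that no other list holds had a median of 0.23 at percentile 95.5, inside the central range. Oxct1, which is needed to use ketone bodies, had a log2 ratio of -0.90 (-1.04 to -0.77). Genes of lipid handling and transport were higher in 11 of 24 cases (10 under scaling to total counts or after length correction) and lower in 0, with a median of 0.74 (percentile 100). Of the 15 that no other list holds, 5 were higher, with a median of 0.56, and several of the shared members, Apoa1 among them, are also markers of absorptive enterocytes. Among the higher genes were the monoacylglycerol lipase gene Mgll, with 8 fed and 282 fasted counts and a log2 ratio of 5.64 (4.64 to 6.86), and the apolipoprotein gene Apoa1, with 2.33 (2.17 to 2.49). Gluconeogenesis genes had a median of 0.76 (percentile 100), with 2 of 8 higher and 0 lower. Pck1 went from 14 to 101 counts, a log2 ratio of 3.35 (2.54 to 4.27), and G6pc from 4 to 20, a log2 ratio of 2.82 (1.24 to 4.83).

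Both lipid synthesis lists lay inside the central range of random lists. Of 14 fatty acid synthesis genes 2 were higher, 1 was lower and 7 had a negative log2 ratio. Their median of -0.03 (percentile 39.3) turned to 0.05 without the low-count filter. Acacb, an acetyl-CoA carboxylase whose product inhibits fatty acid entry into mitochondria, had a log2 ratio of 3.76 (3.38 to 4.18), and the malic enzyme gene Me1 had 2.10. The desaturase gene Scd2 (chromosome 19, 44293674 to 44306864) went from 1187 to 56 counts, a log2 ratio of -3.91 (-4.32 to -3.52). Of 23 cholesterol synthesis genes 0 were higher, 1 was lower and 16 had a negative log2 ratio. Their median was -0.13 (percentile 5.99), and their summed counts gave -0.16 (-0.21 to -0.12). Nsdhl and Idi1, enzymes of the pathway, had -0.50 (-0.81 to -0.19) and 0.58 (-0.15 to 1.31).

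Gasdermin C genes had the lowest ratios of all named genes. Gsdmc4 (chromosome 15, 63891264 to 63912297) went from 268 to 4 counts, a log2 ratio of -5.57 (-7.45 to -4.20). Gsdmc2 went from 185 to 2, a log2 ratio of -6.03 (-9.09 to -4.16), and Gsdmc3 from 122 to 1, a log2 ratio of -6.43 (-11.75 to -3.93). These neighbours are near-identical, so the value of each alone is uncertain. The phospholipase gene Pla2g4c went from 410 to 15 counts, a log2 ratio of -4.27 (-5.13 to -3.54). The NADPH oxidase genes Nox1 and Duox2 had -3.70 (-5.18 to -2.53) and -2.21 (-2.57 to -1.87). Further genes among the 15 lowest were Cd177 (-2.06), Clca4b (-1.75), Pimreg (-2.31), Fam20c (-2.06), Clca3a2 (-1.47), Hoxb6 (-2.15) and Shisa7 (-1.80). Further genes among the 15 highest were the metallothionein gene Mt2 (4.33), Zbtb16 (4.64), Slc25a34 (4.64), Anks6 (3.89) and Akr1b7, which had 2 and 52 counts and a log2 ratio of 5.20 (3.27 to 8.28).

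**Figure D2:**
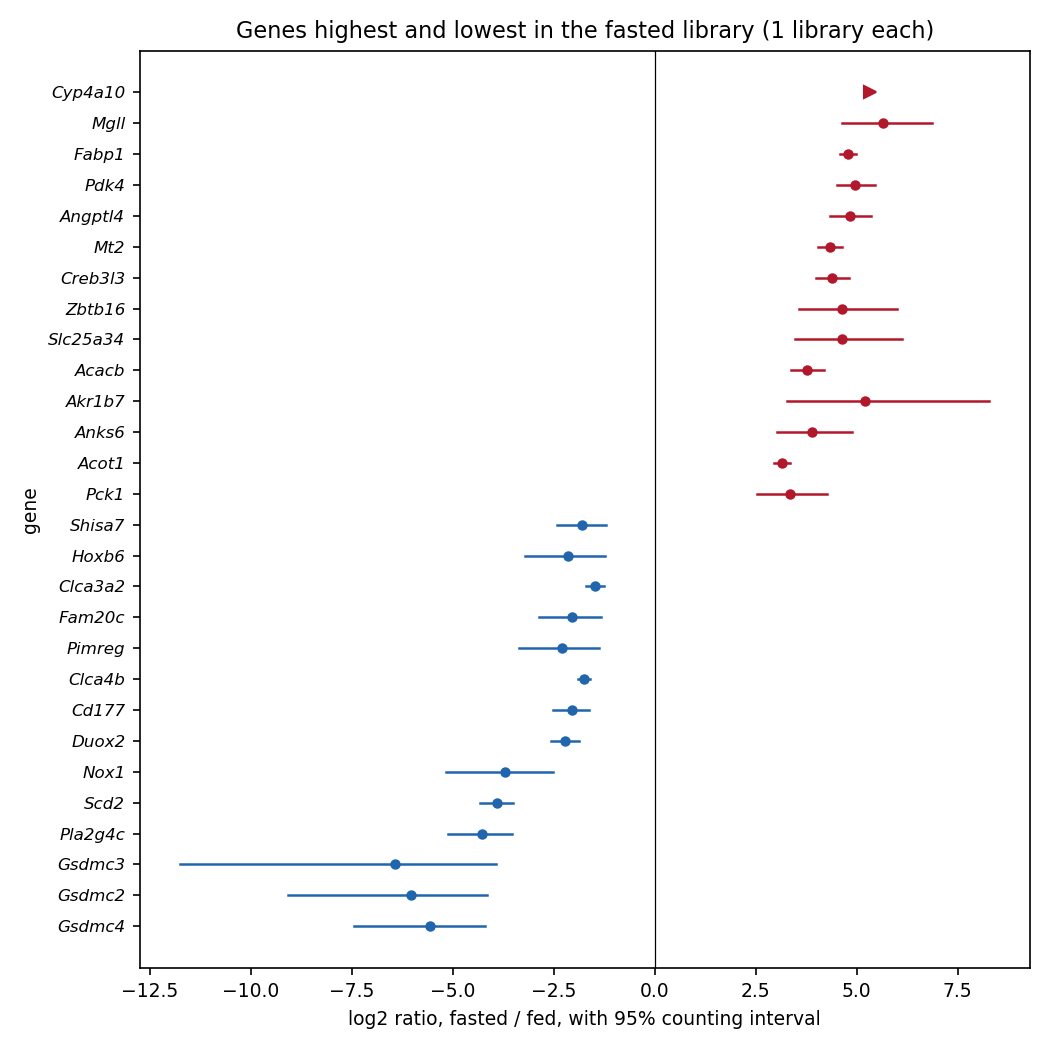
Log2 ratio of fasted to fed for named genes among the 15 highest and the 15 lowest, with bars for the 95% counting interval. The arrowhead for Cyp4a10 marks 40.0-fold, the bound against a floor of 3 counts (its counting interval begins at a log2 ratio of 4.99), and the low genes run from Gsdmc4 at -5.57 to Shisa7 at -1.80 in order of the interval bound nearest to 0.

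Stem cell markers had lower levels as a list, mostly within 2-fold. Of 23 measured markers 0 were higher, 1 was lower and 19 had a negative log2 ratio, with a median of -0.23 (0.853-fold) at percentile 0.01, against -0.52 for their summed counts. Olfm4, an abundant stem cell transcript, went from 100399 to 41452 counts, a log2 ratio of -0.78 (-0.79 to -0.76). Lgr5, the gene of the reporter used for the sort, had -0.49 (-0.57 to -0.40), the WNT-dependent transcription factor gene Ascl2 had 0.10 (-0.04 to 0.25), and Msi1 had -0.40 (-0.55 to -0.26). The marker past 2-fold was the urea transporter gene Slc14a1, with -1.17 (-1.35 to -0.997). WNT target genes, which share 10 of their 17 measured members with other lists, had a median of -0.17 (percentile 1.44), with 0 higher and 1, Apcdd1 at -1.04 (-1.70 to -0.41), lower, a call that ended at -0.89 after correction for exon length. The 7 unshared members had -0.20 at percentile 8.19, inside the central range. Reserve or injury-associated stem cell markers had 0 of 5 higher or lower and a median of 0.08 (percentile 72.2), with Hopx at 0.26 and Tert at -0.68.

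Proliferation genes also had lower levels as a list, all within 2-fold. None of 32 passed the threshold, 24 had a negative log2 ratio and the median was -0.38 (0.766-fold), with 0 of 10000 random lists as low. Mki67, a marker of cycling cells, went from 6214 to 2559 counts, a log2 ratio of -0.78 (-0.85 to -0.72), and the mitotic genes Bub1, Foxm1 and Aurka had -0.82, -0.76 and -0.67. The 8 members with a positive ratio, chosen after their values were seen, were Ccne1, Pcna and the Mcm genes of the list. The largest of these ratios was 0.12, for Mcm2. Cytosolic ribosomal protein genes had the opposite sign. Of 37, 36 had a positive ratio and 0 passed 2-fold, with a median of 0.47 (1.39-fold) at percentile 100, as for Rps14 at 0.71 (0.64 to 0.77). Their reads can be shared with pseudogenes. Ribosome biogenesis genes had 0 of 28 past the threshold and a median of 0.14 (percentile 99.7). Across 11991 genes the log2 ratio correlated with exon length (Spearman -0.245), from a median of 0.15 in the shortest of 10 length bins to -0.14 in the longest.

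Markers of differentiated cells differed by lineage, although both libraries were sorted for high GFP. Absorptive enterocyte markers were higher in 13 of 20 cases and lower in 0, with a median of 1.17 (2.24-fold) at percentile 100. The number higher was 12 under scaling to total counts and 11 after length correction. Fabp2 had a log2 ratio of 1.71 (1.60 to 1.82) and the peptide transporter gene Slc15a1 was 5.65-fold higher, from 13 and 52 counts. Of 11 goblet cell markers 5 were higher and 0 lower, with a median of 0.56 (percentile 100). Among them, Zg16 had 1.63, the trefoil factor gene Tff3 had 1.59, Fcgbp had 1.36 and Ccl9 had 1.03, which became 0.98 after length correction. Paneth cell markers had a median of -0.33 (percentile 0.28), with 2 of 13 higher and 1 lower. The matrix metalloproteinase gene Mmp7 was higher at 2.07 (1.82 to 2.33), and the alpha-defensin gene Defa30, which has near-identical copies, had -0.79 (-0.97 to -0.61). The other Paneth markers past the threshold, chosen after their values were seen, were Mptx1 (higher, 10 to 23 counts) and Defa26 (lower, 30 to 8 counts). Enteroendocrine markers had 0 of 6 past the threshold and a median of 0.19 (percentile 75.8), which turned to -0.09 without the low-count filter, and Chga had -0.86 (-1.73 to -0.04). Tuft cell markers had a median of -0.12 (percentile 40.7), with 1 of 5 higher and 0 lower. Immune cells left 2 measured markers, of which Cd68 was lower (25 to 6 counts, chosen after its values were seen), stroma and endothelium 1, pancreas 1 and red blood cells 0, with none higher.

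Genes that respond to glucocorticoids, hormones released in fasting, had 6 of 13 higher and 0 lower, with a median of 0.81 (percentile 100). Zbtb16 went from 7 to 124 counts, a log2 ratio of 4.64 (3.56 to 5.99). The metallothionein genes Mt2 and Mt1, which are close relatives, had 4.33 (4.05 to 4.63) and 2.04 (1.93 to 2.16). Pdk4 belongs to this list as well as to that of the PPAR targets. Glycolysis genes had 0 of 16 past the threshold and a median of 0.23 (percentile 99.7). Nuclear genes of oxidative phosphorylation had 0 of 30 past it and a median of 0.20 (percentile 99.97), which the correction for exon length brought to 0.10 at percentile 93.6, inside the central range. The mitochondrially encoded genes had 0 of 7 past it and a median of 0.04 (percentile 56.9), which turned to -0.10 after length correction, with mt-Co1 at 0.10.

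The remaining programmes lay inside the central range of random lists when all their members were taken. Amino acid response genes had a median of -0.10 (percentile 16.2) and 0 of 19 past the threshold, and autophagy and lysosome genes had 0.07 (percentile 90.0) and 0 of 28. FOXO targets and insulin-repressed genes had a median of -0.010 (percentile 51.9), with 1 of 17 higher, and unfolded protein response genes had -0.0017 (percentile 55.6), with Herpud1 at 1.12 the 1 of 18 higher. The sign of both of these medians turned under upper-quartile scaling. The higher FOXO gene was Klf15 (13 to 23 counts, chosen after its values were seen). Circadian clock genes had a median of -0.18 (percentile 5.04), and the 13 that no other list holds had -0.24 at percentile 2.43, just outside the range, while length correction gave -0.08 at percentile 21.4 and summed counts gave -0.0041 (-0.08 to 0.07). In the full list, 1 of 14 was higher, which was Dbp (22 to 34 counts, chosen after its values were seen), while Per1 had 0.81 and Per3 -0.79. NRF2 and glutathione genes had 0.14 (percentile 96.7), with Me1 the 1 of 16 higher, and antimicrobial Reg genes had 0.32 (percentile 97.4), with Reg1 at 1.04 the 1 of 5 higher. Length correction ended that call, at 0.86, and brought the Reg median to 0.16. At a minimum of 5 CPM the 4 Reg genes left had a median of 0.0043 (percentile 50.8). None of the heat shock (10 measured, median -0.13, percentile 9.55), immediate early (14, -0.03, 49.8), interferon response (11, -0.16, 16.9), MHC class II (7, -0.12, 14.6) and Notch and secretory commitment genes (11, 0.09, 81.4) passed the threshold. The Notch median turned to -0.0080 at a minimum of 5 CPM. With summed counts in place of the median, the sign also turned for amino acid response (0.09), FOXO target (0.06), unfolded protein response (0.06), heat shock (0.14), Notch (-0.12) and enteroendocrine genes (-0.0017). Of the 34 lists with at least 3 measured members, 12 stood above and 4 below the central range.

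**Figure D3:**
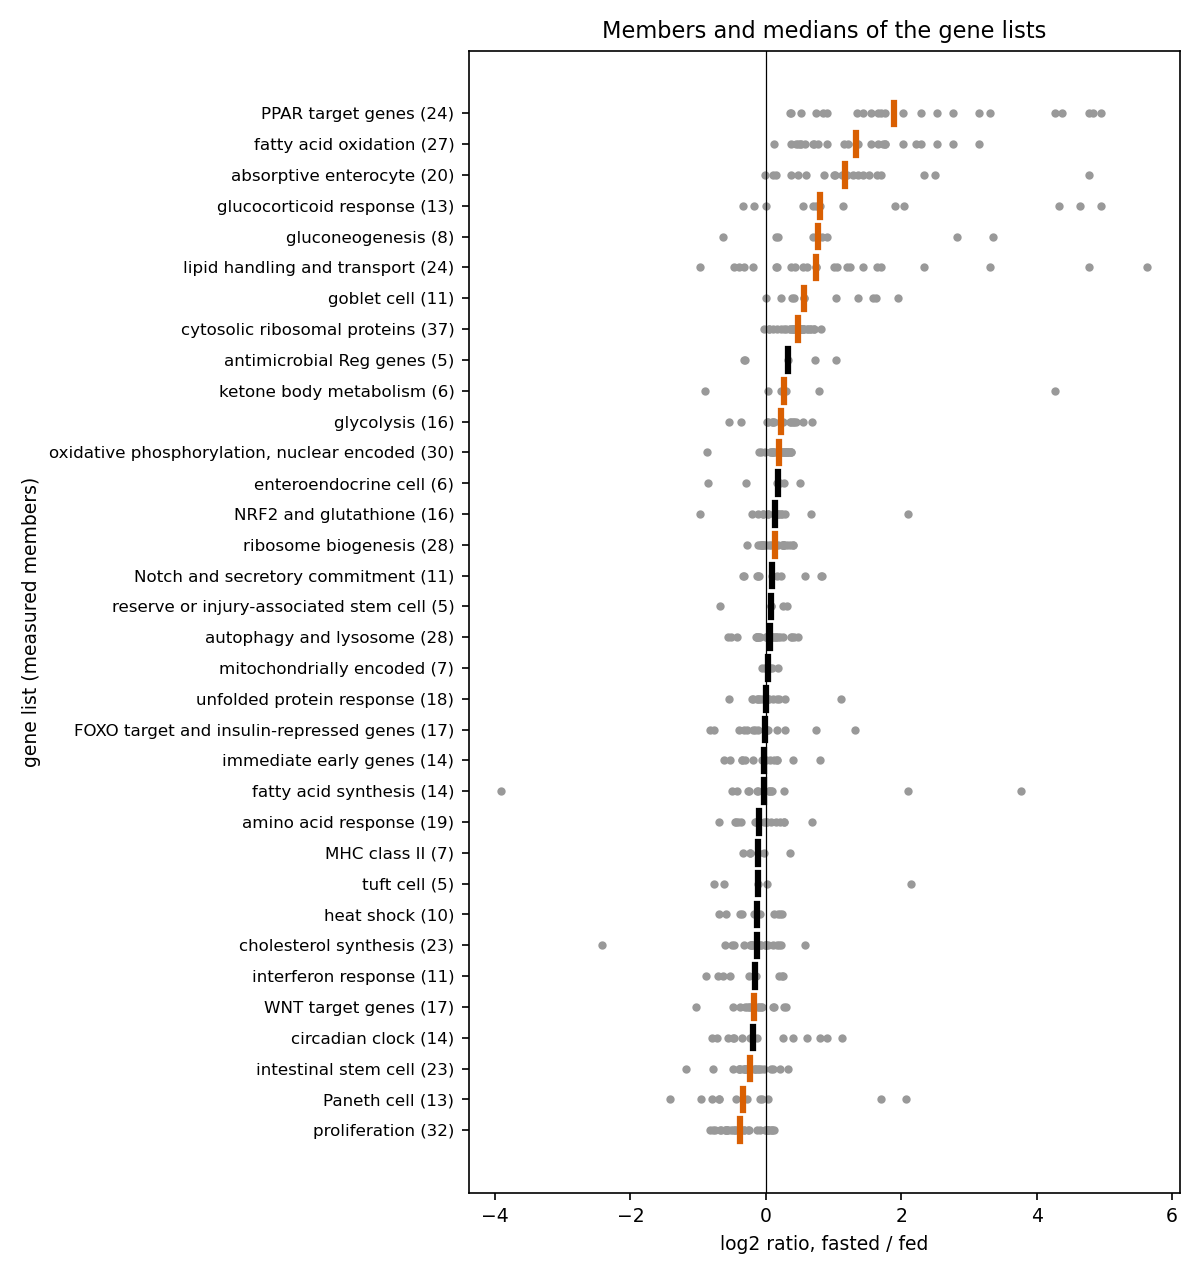
Log2 ratio of fasted to fed for each measured member (grey points) and the median (bar) of the 34 lists with at least 3 measured members, whose number is given in brackets. Cyp4a10, which counts toward the PPAR median, is not drawn. Orange bars mark the lists that stand apart from random lists, from PPAR target genes at 1.89 to proliferation genes at -0.38. The bars of the FOXO and unfolded protein response lists change sign under upper-quartile scaling.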

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

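The length correction and the lists without shared members were chosen after seeing the data. The main counts of 302 higher and 230 lower genes became 176 and 111 at a minimum of 5 CPM, 614 and 607 at 1.5-fold, 124 and 88 at 3-fold, and 103 and 36 when the interval bound itself had to reach 2-fold, as stricter or looser thresholds must. TMM factors, total counts, upper-quartile factors, no filter and the length correction left both counts within 1.5 times. Summed counts in place of the median gave 2.34 for PPAR targets, -0.52 for stem cell markers, which Olfm4 dominates, and 0.85 for enterocyte markers. They also gave 0.43 for gluconeogenesis, 1.63 for glucocorticoid response, 0.99 for goblet cell and -0.20 for Paneth cell genes. For ketone body genes they gave 2.12 against a list median of 0.26, because the 1 higher member dominates the sum. Members that no other list holds gave medians of 0.78 for fatty acid oxidation, 2.91 for PPAR targets, -0.30 for stem cell markers and 1.02 for enterocyte markers. Another scaling shifts the log2 ratios of all genes alike, so it tests nothing about percentiles, and the deposited normalised values equal the scaled counts by construction. Percentiles crossed the central range of random lists with 5 bins for NRF2 and glutathione genes (97.6), without a filter or at 5 CPM for circadian clock (1.71, 1.67, but 21.4 after length correction) and WNT target genes (4.64, 3.23), over members that no other list holds for circadian clock (2.43), WNT target (8.19) and ketone body genes (95.5), and after length correction for WNT target (2.84), oxidative phosphorylation (93.6), heat shock (0.57) and MHC class II genes (0.67). The NRF2 and glutathione list moved inward to percentile 67.1 without a filter and to 65.0 after length correction. Enteroendocrine and tuft cell lists had too few members left at 5 CPM. Of 148 named genes, another scaling moved 4 (mt-Nd1, mt-Co1, mt-Cytb and Olfm4) and the length correction 24 beyond their counting interval, and 0 with a call changed sign. No paired analysis was possible because there is 1 library per group, which also rules out leaving out a replicate or splitting the samples otherwise. Depth limits genes near the floor of 3 counts, and in the least abundant of 5 equal bins of genes counting alone gave an SD of 0.443.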

Other observations

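The peroxisome list, the gene families and the 3 tests of the first pattern below (enterocytes, length for PPAR targets, shared membership) were chosen after the results were seen. The other tests were written before their results were seen, but the values of the single Gsdmc genes were known by then. All genes named here that the naming rule does not cover were chosen after their values were seen. Genes of the peroxisome, an organelle that shortens very long fatty acids, were higher in the fasted library in 10 of 50 cases and lower in 0, with a median log2 ratio of 0.42 (1.33-fold, percentile 100). Without the 8 members that the fixed lists also hold, 7 of 42 were higher and the median was 0.32 (percentile 100). Among the higher ones were Ech1 (2.03), Hsdl2 (2.11), Pxmp4 (2.02), Acot4 (2.31) and Pex11a (1.78). The list was written after Ech1, Hsdl2, Pxmp4 and Pex11a had been seen among the higher genes, so these are no independent evidence of its direction.

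Several low genes belonged to families. The measured Hoxb genes, which mark position along the body axis, had negative log2 ratios in 6 of 6 cases. Counts of all Hoxb genes, unmeasured ones included, summed to 277 in the fed and 51 in the fasted library, a log2 ratio of -1.94 (-2.40 to -1.51). Clca genes differed among themselves. Clca3b went from 30672 to 10505 counts, a log2 ratio of -1.05 (-1.08 to -1.02), Clca1 had -0.0012 (-0.18 to 0.18), and Clca4a went from 2 to 25 counts, 4.14 (2.14 to 7.26). The direction of Clca1 turns under TMM and upper-quartile scaling. Both libraries held Xist, at 14169 and 10936 counts, a log2 ratio of 0.12, and transcripts of the Y chromosome, whose counts summed to 1360 and 569, a log2 ratio of -0.76 (-0.90 to -0.62). The labels give no sex and no number of mice. The share of male cells may thus differ between the libraries, and such a difference could not be told apart from fasting in any of the ratios.

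The first pattern is that fatty acid oxidation, PPAR target and absorptive enterocyte genes were higher in the fasted library. A difference that follows annotated exon length is too small to be the whole cause for PPAR targets. Medians of the 10 length bins ran only from 0.15 to -0.14, so the correction could hardly have come out otherwise. After it the list stayed at percentile 100, with a median of 1.97 against 1.89. The enterocyte markers are not higher through shared genes alone, since the 14 outside the lipid lists stood at percentile 100, with a median of 1.02 and 8 of them higher. Absorptive enterocytes among the cells sorted for high GFP may still account for the pattern. PPAR targets exceeded those markers by 0.872 (0.239 to 2.12, from resampling the genes), yet enterocytes of fasted mice may express more of these targets themselves and were not profiled here, and the abundant enterocyte transcripts Apob (0.14) and Vil1 (-0.01, positive under upper-quartile scaling) were already abundant in the fed library (3261 and 4015 counts), so enterocytes and a response of the stem cells to fasting cannot be told apart.

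The second pattern is that the ribosomal protein list had a median above 0 and the proliferation list a median below 0, with 0 members of either past 2-fold. A trend with exon length is excluded as the whole cause for the proliferation list. After length correction it stayed at percentile 0, with a median of -0.42 against -0.38. The ribosomal protein list stayed at percentile 100, with a median of 0.37 against 0.47, but this cannot exclude transcript length. The correction used all annotated exons of a gene and was held flat below the median of the shortest bin, so it may fall short for short transcripts. A different mix of stem cells and their progeny within the sort, and an effect of fasting on division, remain open and were not tested.

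The third pattern is the 51 genes that were at least 4-fold lower. Counts summed over all Gsdmc genes, unmeasured ones included, went from 576 to 7, a log2 ratio of -5.86 (-7.19 to -4.81). Reads moved between these copies therefore do not account for the low Gsdmc counts. As each measured copy was already known to be low, the sum could not have come out otherwise. Fewer cells of the ileum and colon in the fasted library may contribute. That list, 1 of whose members the fixed lists also hold, had a median of -0.806 at percentile 0.07. Its measured members include Hoxb5, Hoxb7 and Hoxb9 of the family above, and Hoxb7 (-3.46) is itself among the genes to be explained. The median and percentile thus rest in part on the pattern and are no independent support. Summed counts of the list gave -0.22 (-0.39 to -0.05), with Osr2 at -0.33, Fabp6 at -0.20 and Guca2a at 1.05. The resampled interval of -1.34 to -0.196 over 8 genes is too wide to decide, while the proximal small intestine list had 0.20 (percentile 92.5). A weaker interleukin 4 and 13 response of the epithelium could also contribute, but the 5 measured genes of that list, with 2 members in the Paneth cell list, gave -0.188 with an interval of -1.67 to 0.0891, which leaves it open. Fasting itself, which the design names, was not tested apart from these.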
